A study of Homo sapiens with 2 samples.

How the data were processed

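Messenger RNA was profiled by 3' end sequencing in A549 cells, an established human lung adenocarcinoma line. One library came from cells transfected with control siRNAs and 1 from cells transfected with siRNAs against ADGRF4. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Lexogen QuantSeq kit, which primes on the poly(A) tail and reads mainly the 3' end of each transcript. A gene's count is therefore little affected by transcript length, but it depends on which 3' end is used and on how well that stretch of sequence is amplified and mapped.

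The authors deposited whole-number counts per gene symbol, with no normalization in the files. Per the submitters' processing notes, Bowtie2, edgeR and genome build hg19 were used; their roles and versions, the gene annotation, the treatment of reads with several map positions and the strand setting are not given in the sources used here. The files hold 25737 rows with 24462 distinct symbols. There were 286 symbols on more than 1 row (1561 rows, holding 1.21% of the control counts and 1.38% of the knockdown counts), and rows of 1 symbol were summed, a choice made after the repeats were seen. No row lacked a gene symbol. Coordinates are not printed, because the annotation at hand is on GRCh38 and the counts were made on hg19.

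From these counts, library sizes were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. The log2 ratio of a gene was computed as log2 of (knockdown CPM + 1) over (control CPM + 1), with CPM scaled by TMM. This scale understates the change of low genes. Symbols with a mean of at least 30 counts over both libraries were compared, which left 11771. Folds printed for single genes are ratios of scaled CPM without a pseudocount, and the range in parentheses is the exact (Clopper-Pearson) 95% interval of the ratio. These intervals cover counting error only. Duplicate reads from amplification are not independent molecules, and the files carry no molecular identifiers, so the true error is larger.

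With 1 library per group there is no replicate check, and no test between the treatments and no p-value is given. Every difference is between these 2 libraries. A gene is called higher or lower by size alone: 2-fold for single genes, and 1.5-fold for members of a list. The number of 2-fold genes that counting error alone would give was taken from 100 Poisson draws. Before the data were examined, 40 gene lists and the rule for the genes named in the text were fixed. That rule takes ADGRF4 and the 12 highest and 12 lowest ratios among symbols with a mean of at least 100 counts. Symbols that are LOC numbers, LINC, MIR, SNOR or RNU names, chromosome open reading frames or names with an AS suffix were passed over, and ACTB and GAPDH were added as reference genes. For each list the rule takes up to 4 compared members with the largest absolute log2 ratio. Older symbols were matched. The median of each list with at least 3 compared members was set against the medians of 10000 random lists of the same size, matched on mean count in 20 bins. Its percentile describes these libraries and is not a test of the treatment.

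After a trend with base composition was seen, the GC content of the last 300 bases of the longest transcript in GENCODE 29 (GRCh38) was taken for each symbol. A value was found for 11149 compared symbols (94.7%). Ratios were also centred on the median within 20 bins of this 3' GC content, and list percentiles were recomputed with random lists matched on count (5 bins) and 3' GC (10 bins). The same annotation gave named processed pseudogenes and exons overlapped by a gene on the other strand. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

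Counts simulated for the knockdown and control libraries over 11767 genes, with counting error and set changes only, were used to test the ratio calculation. With 4-fold changes, 100.0% of the changed genes were called in each direction. At 2.5-fold, 100.0% of higher and 95.8% of lower genes were called, and 0 unchanged genes were called. The intervals held the true ratio for 95.8% of genes. Of unchanged random lists, 7.5% lay outside the central 95%. Too few such lists were simulated to tell this share from the one that chance should give. For these lists independent noise was added to each gene, with no GC trend and no related members. The share therefore does not cover lists whose members vary together.

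Alternatives were total-count scaling, DESeq2 1.42.0 size factors, upper-quartile scaling, pseudocounts of 0.1 and 5, other count limits and fold thresholds, and thinning of the control library to the knockdown total. Centring on 3' GC content and keeping the rows of 1 symbol apart were added after the data were seen. Under total-count scaling, every log2 ratio shifts by -0.15 before the pseudocount, and the median compared gene lies at -0.16 instead of -0.02. None of the 13 mitochondrially encoded genes on the fixed lists was analysed here, because no symbol matched.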

Results

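The study asked how silencing of ADGRF4, an adhesion G protein-coupled receptor, alters gene expression in A549 lung adenocarcinoma cells. It holds 2 libraries of 3' end counts, 1 from cells given control siRNAs and 1 from cells given ADGRF4 siRNAs. The control library held 10396047 counts and the knockdown library 9825320. A count was found for 17190 and 17193 symbols, respectively, and the 10 most abundant symbols took 7.25% and 7.95% of the counts. MALAT1, a nuclear long non-coding RNA, took 2.13% of the control counts and 0.969% of the knockdown counts. There was no replicate of either treatment, so each difference below is between 2 libraries, and its stated range covers counting error only.

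ADGRF4 itself was almost unread in these cells. It had 3 counts in the control library (exact Poisson 95% interval 0.619 to 8.77) and 1 count in the knockdown library (0.0253 to 5.57). Without TMM factors these equal 0.289 and 0.102 CPM of the library totals, against 0.289 and 0.305 CPM for the 3 counts that a count of 0 still allows. Both libraries lay at or under that limit, so no fold is given, and a loss of the target was not detectable at this depth. The labels of the libraries are therefore not checked by the silenced gene.

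The largest differences were towards lower counts after ADGRF4 siRNA. TMSB4X, which sequesters actin monomers, had 4512 counts in the control and 139 in the knockdown library, 27.7-fold lower (23.4 to 33.0). PFN1, a profilin that also binds actin, was 12.2-fold lower (10.7 to 13.9). CYR61, a matricellular protein, was 18.6-fold lower (13.0 to 27.7), and PKDCC, a secreted kinase, was 22.5-fold lower (15.6 to 33.6). The cytokine IL18 was 12.9-fold lower (8.30 to 21.1), the kinase PIM1 12.5-fold lower (8.55 to 18.8) and the tetraspanin CD9 13.3-fold lower (8.54 to 21.7). The other named genes on this side were ARHGEF2, 11.3-fold lower, with DTD1 12.3-fold, DERA 13.5-fold and FLJ44635 17.9-fold lower, and METTL17 lower by 10.1-fold to 35.3-fold.

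The highest ratios were smaller. IL32, a cytokine, had 76 and 323 counts and was 4.99-fold higher (3.87 to 6.49) after ADGRF4 siRNA. BCL2L1, which encodes the anti-apoptotic protein BCL-XL, was 3.77-fold higher (3.53 to 4.03), and BCAM, a laminin receptor, was 3.72-fold higher (3.28 to 4.23). NRGN, a calmodulin-binding protein, was 4.38-fold higher (3.63 to 5.31), and DEGS2, an enzyme of sphingolipid synthesis, was 4.24-fold higher (3.22 to 5.64). LRSAM1, CACFD1, NCDN, INAFM1, AMH, PRR7 and WDR38 were between 3.45-fold and 3.95-fold higher. After centring on 3' GC content, the log2 ratios of CACFD1 (0.98), INAFM1 (0.96), AMH (0.93) and PRR7 (0.93) no longer reached 2-fold. Those of BCAM (1.00), LRSAM1 (1.04) and WDR38 (1.04) only just did. Exons of WDR38 are overlapped on the other strand by RPL35, those of NCDN by KIAA0319L, those of DEGS2 by EVL, those of BCL2L1 by ABALON and those of PFN1 by ENO3. NRGN, METTL17 and ARHGEF2 are also overlapped by other annotated genes on the other strand. The reads of such pairs could not be told apart if strand was not used in counting. TMSB4X and PFN1 also have 5 and 10 named processed pseudogenes that can share their reads.

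Across the 11771 symbols compared, 923 (7.84%) were at least 2-fold higher after ADGRF4 siRNA and 1219 (10.4%) at least 2-fold lower. With total-count scaling the split was 556 higher and 1563 lower. At 4-fold the difference in direction was wider, with 7 symbols higher and 162 lower. Counting error alone gave on average 0.27 symbols that were 2-fold apart, and at most 2, in 100 draws. The SD of the log2 ratios was 0.77, against 0.15 for counting error. In the 1177 symbols with the most counts, it was 0.73 against 0.038.

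**Figure D1:**
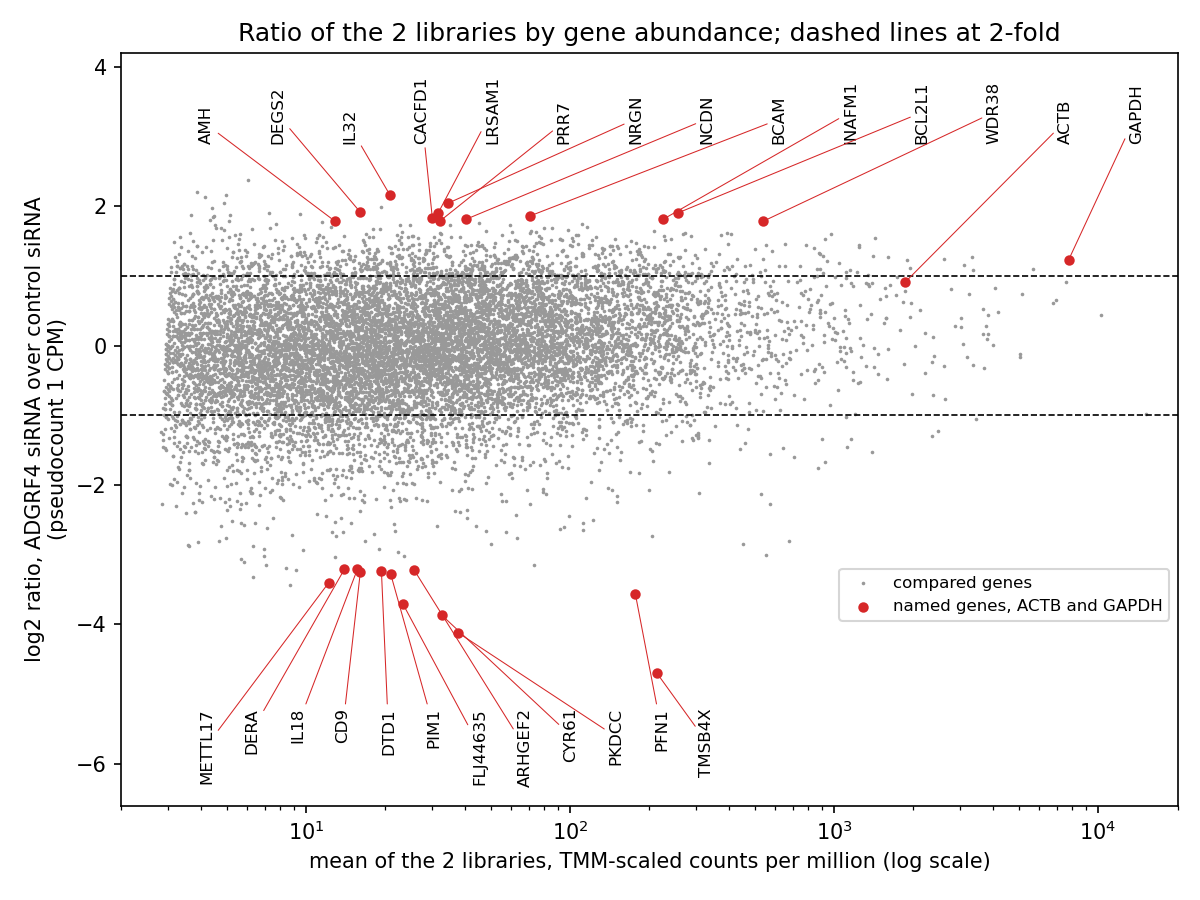
Log2 ratio of the ADGRF4 siRNA library over the control siRNA library (vertical axis, pseudocount 1 CPM) against mean TMM-scaled CPM (horizontal log axis). Each grey point is 1 of 11771 compared symbols, red points are the named genes with ACTB and GAPDH, and dashed lines mark 2-fold; the lowest ratio is -4.70 and the highest 2.38.

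Common reference genes differed between the libraries as widely as other genes. GAPDH, a glycolytic enzyme, was 2.35-fold higher (2.32 to 2.37) and ACTB, cytoplasmic actin, 1.88-fold higher (1.84 to 1.92) after ADGRF4 siRNA. They have 61 and 9 named processed pseudogenes, and centring on 3' GC left a log2 ratio of 0.63 for GAPDH. EEF1A1, a translation elongation factor with 37 named processed pseudogenes, was 6.99-fold lower (6.63 to 7.37), EMC7 4.12-fold lower and HPRT1 3.20-fold lower. Of the 28 reference genes, 3 were at least 1.5-fold higher, 9 lower and 16 between, and the SD of their log2 ratios was 0.87, wider than the 0.77 of all compared symbols. Their median of -0.27 lay at percentile 0.80 of random lists matched on count and at 0.59 when the lists were also matched on 3' GC content. By comparison, 21.1% of all compared symbols were at least 1.5-fold higher and 22.3% lower.

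The ratio followed the base composition of the transcript's 3' end. In the 1115 genes with the lowest 3' GC content (median 27.0%), the median log2 ratio was -0.35, and 1.08% of genes were at least 2-fold higher against 14.2% lower. In the 1115 with the highest (median 60.7%), the median was 0.78, with 32.6% higher and 1.79% lower. After the ratios were centred on 3' GC, 381 symbols were at least 2-fold higher and 1051 lower. Without centring, the same 11149 symbols gave 872 and 1159.

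**Figure D2:**
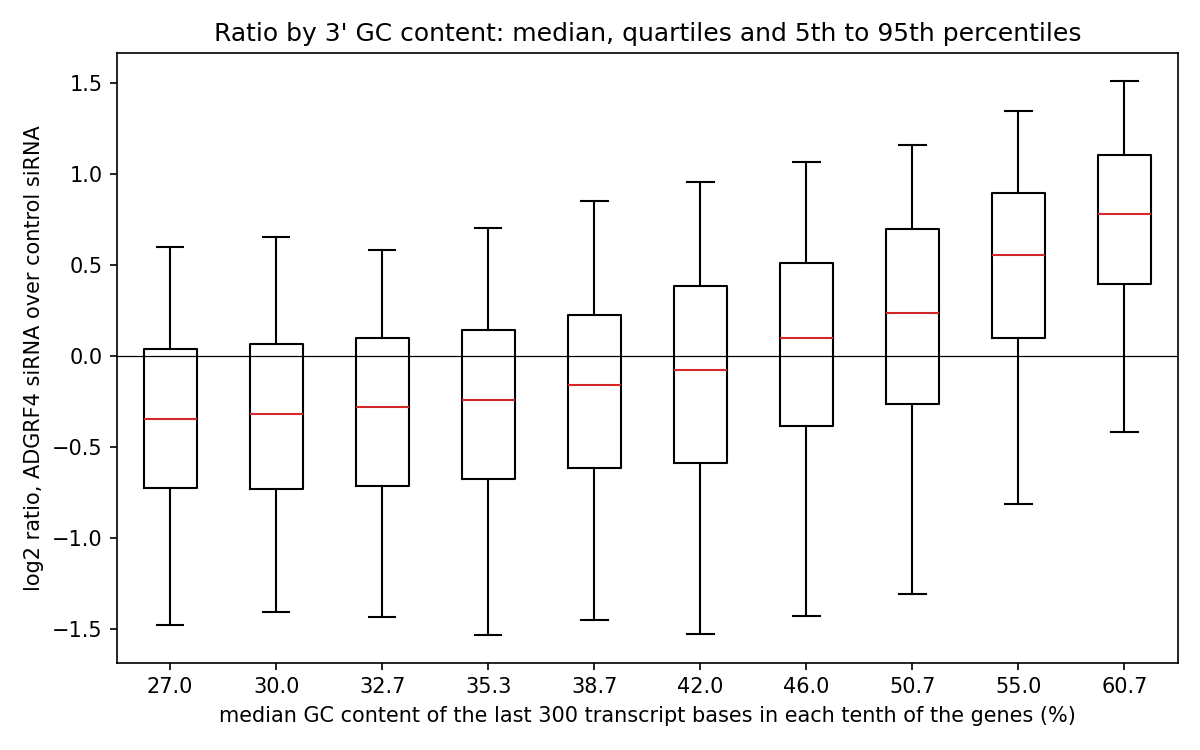
Log2 ratio of the ADGRF4 siRNA library over the control siRNA library (vertical axis) in 10 groups of nearly equal size, made from the compared genes by GC content of the last 300 transcript bases (horizontal axis, median percent of each group). Red lines are medians, boxes are quartiles and whiskers run from percentile 5 to percentile 95; the medians run from -0.35 at 27.0% GC to 0.78 at 60.7% GC.

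Cytokine and NF-kB target genes were lower on balance after ADGRF4 siRNA. Of the 24 compared, 11 were at least 1.5-fold lower, 5 higher and 8 between. IL18 is among them, and the chemokines CXCL2 and CCL2 were 7.12-fold lower (4.98 to 10.5) and 7.28-fold lower (4.25 to 13.4), whereas IL32 was higher. The list's median of -0.42 lay at percentile 1.12 of random lists matched on count and at 1.48 when 3' GC was matched too, and was -0.22 with no count limit. Antigen presentation genes gave 6 lower, 3 higher and 6 between among 15. PSMB8, an immunoproteasome subunit, was 5.74-fold lower (3.32 to 10.6), ERAP1, which trims peptides, 2.66-fold lower and the chaperone CALR 2.28-fold lower, while TAPBP was 2.18-fold higher. Their median of -0.52 (bootstrap interval over genes -0.99 to 0.37) lay at percentile 0.92, and at 0.155 with 3' GC matched, and was -0.15 with no count limit. Both lists lay near the percentile of the reference genes, 0.80.

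Of 20 TGF-beta targets, 9 were at least 1.5-fold lower, 3 higher and 8 between. BHLHE40, a transcriptional repressor, was 3.31-fold lower (2.78 to 3.97), ID3, an inhibitor of basic helix-loop-helix factors, 3.04-fold lower (2.74 to 3.38) and IGFBP3 2.52-fold lower, but TGFB1 itself was 2.74-fold higher (2.23 to 3.39). The median of -0.43 (bootstrap interval -0.92 to 0.19) lay at percentile 0.69, near the 0.80 of the reference genes, and at 1.27 with 3' GC matched. Of 22 immediate early genes, 10 were lower, 2 higher and 10 between. NR4A1, an orphan nuclear receptor, was 7.15-fold lower (6.01 to 8.56), MYC 5.60-fold lower (3.52 to 9.34) and KLF10 3.73-fold lower (3.13 to 4.46), beside CYR61. The list's median of -0.29 lay at percentile 2.85, inside the central 95%, and at 10.2 with 3' GC matched. SIK1, a kinase induced by cAMP, was 6.44-fold lower (5.27 to 7.92), and 6 of 13 cAMP and CREB targets were lower with 0 higher (median -0.46, percentile 3.46).

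Other signalling lists held large differences in single genes, with medians inside the central 95% of random lists matched on count. HES1, a Notch target, had 8707 and 1024 counts and was 7.25-fold lower (6.79 to 7.74). In the Wnt and Notch list, 7 of 18 genes were lower and 4 higher; ZNRF3 was 3.82-fold lower and DKK1 3.41-fold lower. Among 16 MAPK feedback genes, 6 were lower and 2 higher. DUSP6, an ERK phosphatase, was 3.40-fold lower (2.72 to 4.28), the receptor EPHA2 3.14-fold lower, and IER3 2.17-fold higher. The ERBB list gave 3 lower and 2 higher among 14, with NRG4 3.71-fold lower and AXL 1.99-fold higher. Of 22 YAP targets, 8 were lower and 3 higher; CTGF was 2.18-fold lower and TEAD4 2.44-fold higher. The medians of these lists were -0.31, -0.31, -0.20 and -0.24 (percentiles 11.8, 8.37, 15.9 and 7.56). After centring on 3' GC they were -0.30, -0.17, -0.10 and -0.065; with no count limit the Wnt and Notch median was -0.12 and the YAP median -0.44.

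Keratins and mucins were the only fixed list whose median lay above the central 95% of random lists matched on count. Of the 12 compared, 8 were at least 1.5-fold higher after ADGRF4 siRNA and 1 lower. KRT7 was 2.66-fold higher (2.59 to 2.74), the secreted mucin MUC5AC 2.39-fold higher (2.27 to 2.53), KRT81 2.22-fold higher and MUC1 1.94-fold higher. The median was 0.71 (percentile 99.5). These genes have GC-rich 3' ends, with a median of 57.0% GC. With 3' GC matched the list lay at percentile 76.4, and its centred median was 0.24. With no count limit the median was 0.45.

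Genes of cell junctions and of the matrix went both ways. CDH1, which encodes E-cadherin, was 4.34-fold lower (3.78 to 5.01), and the junction genes JUP and DSC2 were 2.56-fold and 2.69-fold lower, whereas PKP3, a plakophilin, was 2.77-fold higher. Of 19 epithelial genes, 7 were lower and 3 higher (median -0.12, percentile 29.6, and 0.12 after centring on 3' GC). The mesenchymal marker VIM was 2.36-fold lower (2.22 to 2.51), and 12 of 14 mesenchymal genes lay between the limits, with 1 higher and 1 lower (median 0.15, percentile 66.2). Among 18 laminin and hemidesmosome genes, 5 were higher and 4 lower. BCAM, ITGA3 (2.02-fold) and ITGB4 (1.96-fold) were higher, and the laminin chain LAMB3 was 2.68-fold lower (2.18 to 3.30). Centring on 3' GC left log2 ratios of 1.00 for BCAM, 0.26 for ITGA3 and 0.23 for ITGB4. The median was -0.13 (percentile 16.9, and 1.46 with 3' GC matched). Integrin and focal adhesion genes gave 6 lower and 4 higher among 27 (median -0.087, percentile 17.3), with FERMT2, a kindlin, 3.53-fold lower and ITGA5 3.14-fold higher. Of 14 matrix proteases and inhibitors, 4 were lower and 3 higher (median -0.11, percentile 28.9, but 0.37 at a limit of 100 counts). The urokinase receptor PLAUR was 3.50-fold lower (3.18 to 3.85), PLAU, which encodes urokinase, 2.67-fold lower and the cathepsin CTSL 3.79-fold lower.

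Among the 12 other adhesion G protein-coupled receptors with enough counts, 3 were at least 1.5-fold lower, 1 higher and 8 between. CELSR1 was 2.81-fold lower (2.06 to 3.88), ADGRA2 2.71-fold lower and ADGRL2 1.93-fold lower, while CELSR2 was 1.77-fold higher. The median was 0.0040 (percentile 60.4). A further 18 members were under the count limit, 12 of them with at most 3 counts in each library.

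Mitotic genes were lower on balance after ADGRF4 siRNA. Of 39 G2 and mitosis genes, 12 were at least 1.5-fold lower, 4 higher and 23 between. The kinetochore gene NUF2 was 2.54-fold lower (2.16 to 2.99), the kinesin KIF20A 2.44-fold lower, the cyclin CCNB2 2.36-fold lower and the checkpoint kinase BUB1 2.61-fold lower. The median of -0.36 lay at percentile 0.16. These genes have 3' ends of 32.0% median GC, and with 3' GC matched the list lay at percentile 1.30, with a centred median of -0.20. The reference genes lay no higher, at percentile 0.59 with 3' GC matched and a centred median of -0.27. G1/S and replication genes gave 9 lower, 6 higher and 20 between among 35 (median -0.022, percentile 34.7). CCNE2 was 4.37-fold lower and MCM2 2.95-fold lower, whereas MCM5 was 2.62-fold higher. In the list of cell cycle inhibitors, 4 of 10 were lower and 1 higher (median -0.31, percentile 12.7, and -0.0060 at a limit of 100 counts), with RB1 4.10-fold lower and the cyclin-dependent kinase inhibitor CDKN1B 1.95-fold lower.

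Apoptosis and p53 target genes held differences of both signs. CASP8 and CASP9, initiator caspases, were 10.8-fold lower (5.49 to 24.2) and 14.1-fold lower (5.24 to 53.2), from 114 and 66 counts in the control to 9 and 4 counts. BCL2L1 and BAK1, which act in opposite directions in apoptosis, were both higher, BAK1 by 3.40-fold (2.33 to 5.05). Of 20 apoptosis regulators, 8 were lower and 5 higher (median -0.35, percentile 2.93, but -0.096 after centring on 3' GC and -0.042 at a limit of 100 counts). Of 27 p53 targets, 10 were higher and 4 lower (median 0.056, percentile 58.6). SESN2 was 2.52-fold higher and PHLDA3 1.94-fold higher, and PLK2 was 2.68-fold and CCNG1 2.26-fold lower.

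Stress and metabolic lists gave medians inside the central 95% of random lists matched on count. Of 37 NRF2 targets, 13 were lower and 9 higher (median -0.0097, percentile 13.98). The aldo-keto reductases AKR1B10 and AKR1C1 were 4.86-fold lower (4.63 to 5.11) and 2.93-fold lower, NR0B1 was 17.5-fold lower (8.30 to 44.4), and HMOX1, heme oxygenase, had 829 and 2051 counts (2.68-fold to 3.15-fold higher). Among 36 genes of the unfolded protein response and ATF4, 12 were higher and 8 lower (median -0.031, percentile 22.7); CBS was 3.40-fold higher, CTH lower by 3.09-fold to 5.79-fold and MANF 3.34-fold lower. Heat shock genes gave 6 lower and 3 higher among 20 (median -0.21, percentile 4.16). HSPB8 had 78 and 1 counts, 66.5-fold lower (11.6 to 2660), BAG3 was 3.84-fold lower and STIP1 2.63-fold higher. In the hypoxia and glycolysis list, 10 of 33 were higher and 7 lower (median -0.047, percentile 21.5). The glycolytic genes ALDOA and PFKL were 2.92-fold and 2.47-fold higher, and CA9, a carbonic anhydrase, had 83 and 2 counts, 35.4-fold lower (9.49 to 297).

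Lipid genes were split evenly or nearly so. Cholesterol synthesis gave 5 lower and 5 higher among 25 (median 0.0062, percentile 47.3), with CYP51A1 2.70-fold and HMGCS1 2.24-fold lower. Fatty acid genes gave 5 lower and 6 higher among 23 (median 0.078, percentile 52.4); the lipase PNPLA2 was higher by 2.60-fold to 3.23-fold and the desaturase FADS2 2.24-fold lower. Interferon-stimulated genes, which can respond to transfected RNA, gave 5 higher and 4 lower among 21 (median -0.029, percentile 56.0), with IFI35 2.36-fold higher and EIF2AK2 2.16-fold lower. All 16 genes of the small RNA machinery lay between the limits (median -0.040, percentile 43.3).

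Ribosomal protein genes, which encode subunits of 1 complex, scattered about as widely as other genes. Of 78, 17 were at least 1.5-fold lower and 15 higher, with an SD of 0.78 against 0.77 for all compared symbols. Of all compared symbols, 22.3% were lower and 21.1% higher by that limit. RPL34 was 4.39-fold lower (4.18 to 4.62), RPL30 3.39-fold lower and RPL4 3.20-fold lower, although each had over 1000 counts in both libraries. The median of -0.080 (bootstrap interval -0.26 to 0.16) lay at percentile 0.21, where the central 95% of medians of random lists matched on count ran from 0.0083 to 0.41, and at 0.02 with 3' GC matched. Many ribosomal protein genes have processed pseudogenes, so their counts are uncertain. The median was 0.41 for the 26 with 1 to 4 named copies and -0.16 for the 51 with 5 or more. After centring on 3' GC these were -0.097 and -0.29. Nuclear genes of oxidative phosphorylation gave 19 lower and 14 higher among 66 (median 0.043, percentile 15.3), with NDUFB3 7.90-fold and SDHB 5.18-fold lower. Histone genes gave 4 lower and 1 higher among 13 (median 0.0025, percentile 36.3, but -0.32 after centring on 3' GC), and lysosome and autophagy genes 7 lower and 7 higher among 33 (median 0.036, percentile 48.5).

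Leukocyte, endothelial and fibroblast markers were mostly under the count limit. Among the leukocyte markers, 14 of the 18 under the count limit had at most 3 counts in each library, as did 11 of 13 endothelial and 8 of 12 fibroblast markers. The compared leukocyte genes were CD14, 1.28-fold lower (0.788 to 2.10), and CD68, 1.12-fold lower (0.927 to 1.35). EGFL7 was the compared endothelial gene, 1.77-fold higher (1.24 to 2.54), a direction that turned after centring on 3' GC. Of the 4 compared fibroblast genes, 2 were higher, COL6A2 by 5.55-fold (3.15 to 10.4) and FBLN1 by 2.33-fold (2.12 to 2.56), with a median of 0.68 (percentile 96.7, or 80.3 with 3' GC matched, and 0.15 with no count limit). Alveolar type II genes gave 1 higher and 0 lower among 6 (median 0.10, percentile 64.1), and the higher gene, ABCA3, lay at -0.011 after centring on 3' GC. Airway secretory and basal genes gave 3 higher and 1 lower among 6 (median 0.67, percentile 95.8, but 0.17 after centring and 78.8 with 3' GC matched), with AGR2 3.09-fold lower (2.72 to 3.52) and MUC5AC higher.

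**Figure D3:**
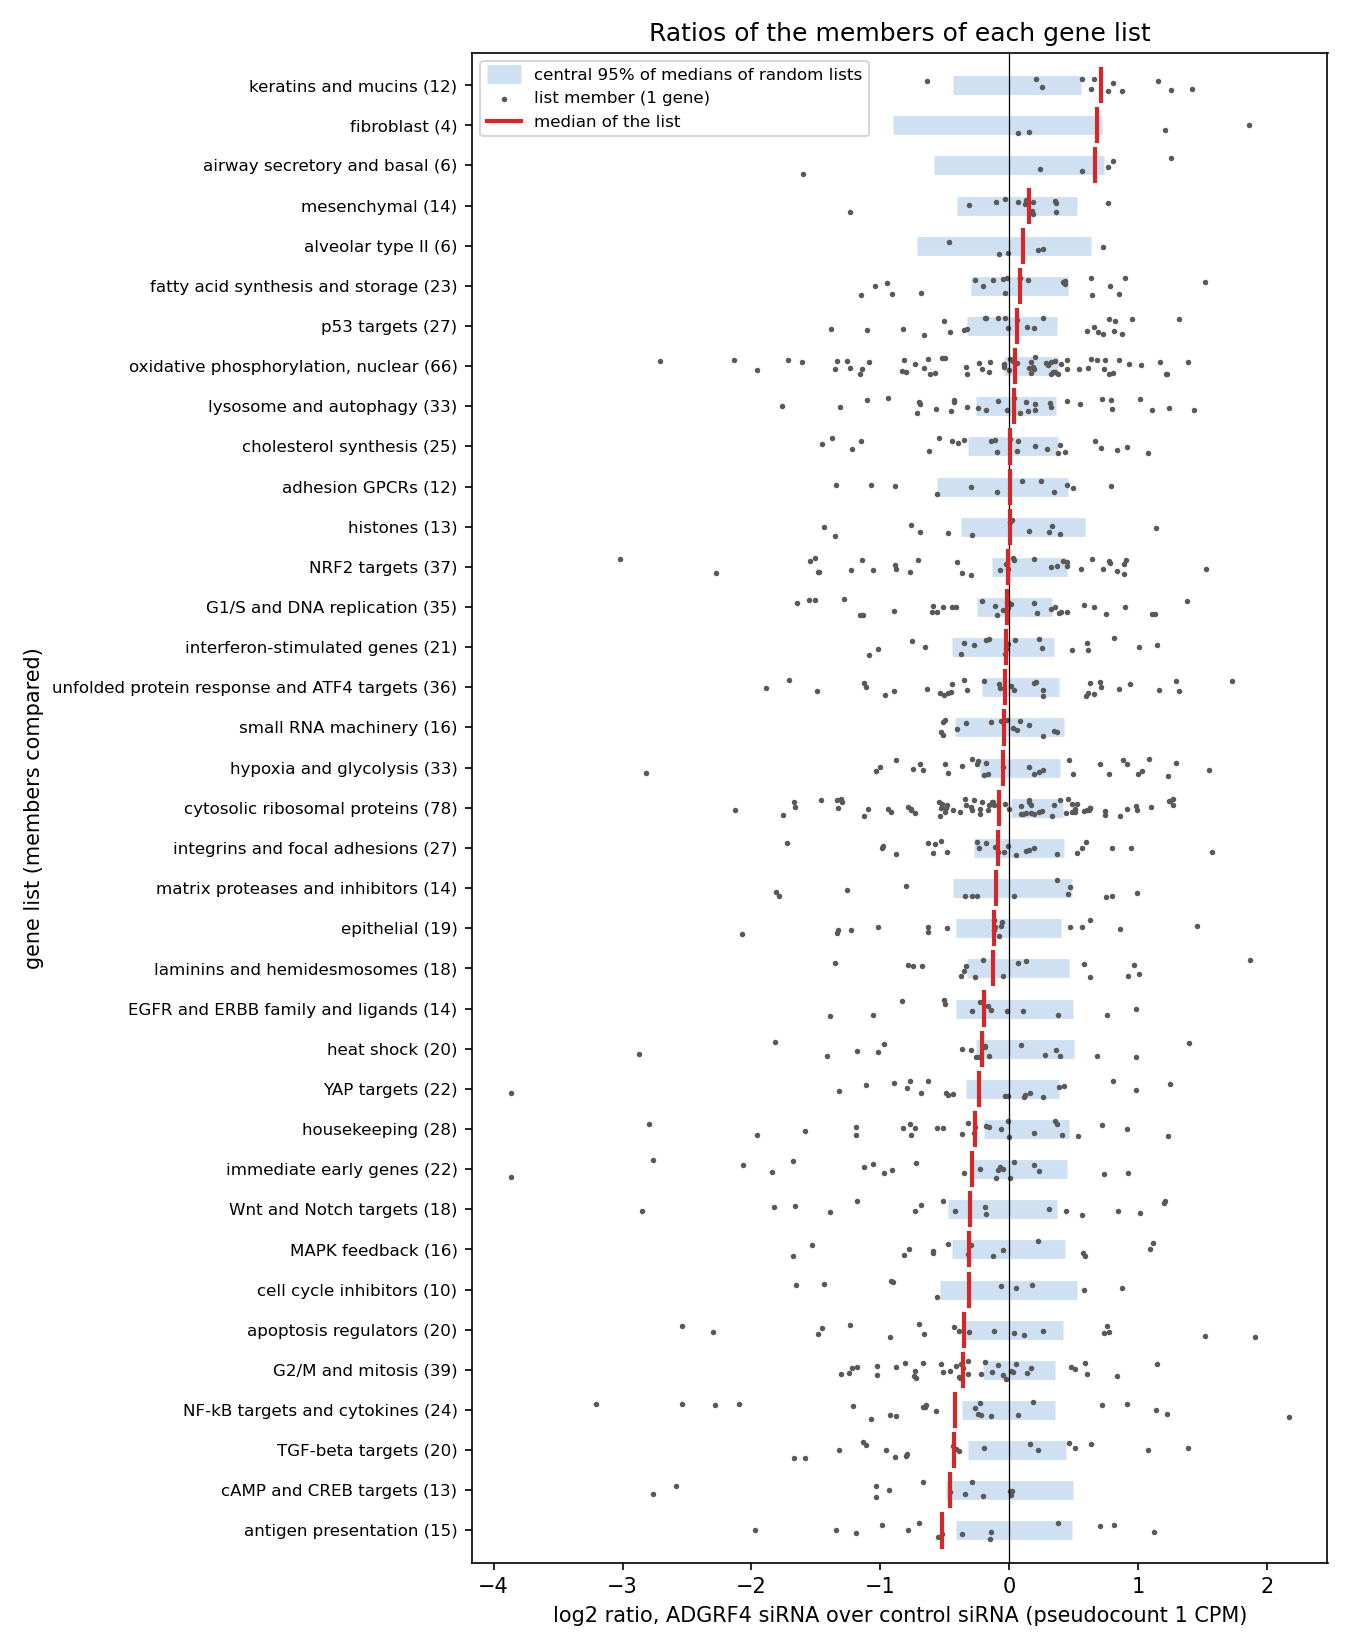
Log2 ratios of the ADGRF4 siRNA library over the control siRNA library (horizontal axis) for the members of 37 gene lists (vertical axis, number compared in parentheses). Points are genes, red lines list medians and blue bars the central 95% of medians of random lists matched on count; 6 list medians lie below their bar and 1, keratins and mucins, above.

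Of the 37 lists with at least 3 compared members, 6 medians lay below the central 95% of random lists and 1 above it. If lists were random draws, 1.85 are expected outside, or 2.77 at the share of unchanged lists found outside in simulation. Both numbers assume unrelated members, which these lists do not have. The 6 were antigen presentation, TGF-beta targets, NF-kB targets and cytokines, G2 and mitosis, cytosolic ribosomal proteins and the reference genes. With 3' GC matched as well, 7 lay below and 0 above, and the 6 remained among the 7, joined by laminins and hemidesmosomes. The size of a list's median depended on the settings: of the 37, 35 moved by over 1.5 times or turned sign under at least 1 alternative, and 15 turned sign. Medians near 0 have no firm direction: those of adhesion receptors, p53 targets, cholesterol and fatty acid genes, oxidative phosphorylation, histones, lysosome and alveolar type II genes were above 0 and turned negative under total-count scaling. After centring on 3' GC, the named genes MUC5AC, KRT81, MUC1, MCM5, IFI35, TAPBP and PFKL, which were higher, and ADGRL2, which was lower, were no longer 1.5-fold apart. GAPDH, IER3, PKP3, KRT7, ITGA5, TEAD4, SESN2, BAK1, STIP1, ALDOA and PNPLA2 on the higher side, and VIM, CTGF, NUF2, KIF20A, BUB1, CCNG1, EIF2AK2 and HMGCS1 on the lower, were no longer 2-fold apart. Many genes named from the lists, among them ADGRA2, NRG4, KRT7, VIM, BHLHE40, IER3, DKK1, CYP51A1, TGFB1, PLAU, CCNE2, MCM2, NUF2, KIF20A, PSMB8, ERAP1, CASP9, BAK1, EIF2AK2, CA9, FADS2, RPL4 and NDUFB3, have exons overlapped by another annotated gene on the other strand. Their values are uncertain if strand was not used in counting.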

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

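The 2-fold counts, 923 higher and 1219 lower, kept within 1.5 times of these values with DESeq2 size factors, upper-quartile scaling, a pseudocount of 0.1, no count limit, a limit of 10, thinning of the control library, a counting interval that excludes 1, and rows of 1 symbol kept apart. Total-count scaling gave 556 higher, by construction, since it lowers every ratio. A pseudocount of 5 gave 528 higher and 699 lower, by construction, since it pulls low genes together. A limit of 100 counts left 811 lower, with fewer genes compared. Centring on 3' GC content, chosen after seeing the data, gave 381 higher and kept the lower count within 1.5 times. A 1.5-fold threshold gave 2482 higher and 2624 lower, and a 3-fold threshold 73 and 379. Of 48 list medians, 48 stayed within their bootstrap interval under each of 7 planned settings and 47 under total-count scaling, where zinc finger genes left theirs. Zinc finger genes (-0.019) and solute carriers (-0.034), both outside the central 95% of random lists before, turned sign there. These intervals are wide, and staying within them fixes neither size nor sign. Of the 37 medians of lists fixed beforehand, 35 moved by over 1.5 times or turned sign under at least 1 setting: 26 under 3' GC centring, 25 under total-count scaling, 18 with no count limit and 18 at a limit of 100 counts. A sign was turned in 15, and of the 11 families chosen later, 10 moved and 5 turned. Under 3' GC centring 46 stayed, keratins and mucins and epithelial genes did not, the latter from -0.12 to 0.12, and solute carriers turned sign (-0.027). Of 206 single genes under that centring, 129 moved outside their counting interval and 4 whose interval excluded 1 turned sign: ABCA3 (-0.011), MUC5B (-0.057), SPDEF (-0.091) and EGFL7 (-0.14); the cause was not tested. No single gene whose interval excluded 1 turned sign under the planned settings; COL1A1, whose interval held 1, did under total-count scaling. ADGRF4 had too few counts for a ratio under any setting. With 1 library per group, no replicate could be left out. Depth limits statements on genes under 30 mean counts, ADGRF4 among them.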

Other observations

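The gene families described first were chosen by symbol after the data were seen. Of 9 humanin-like genes, nuclear copies related to mitochondrial ribosomal RNA, 5 were at least 1.5-fold higher after ADGRF4 siRNA, 1 lower and 3 between. MTRNR2L7 was 3.49-fold higher (2.99 to 4.09) and MTRNR2L3 3.21-fold higher (2.77 to 3.72), and the median log2 ratio of 1.03 lay at percentile 99.98 of random lists matched on count. These genes are near-identical to each other, so their single values are uncertain. Their median and percentile are uncertain too, since the percentile takes the 9 as independent genes. Of 25 heterogeneous nuclear ribonucleoprotein genes, which bind pre-mRNA, 11 were lower and 2 higher, with HNRNPF 6.41-fold lower (5.66 to 7.29) and HNRNPL 3.64-fold lower. Their median of -0.39 lay at percentile 0.13 and at 0.78 with 3' GC matched, and was -0.21 with no count limit. Proteasome subunits gave 14 lower and 8 higher among 37 (median -0.17, percentile 3.16, and 1.57 with 3' GC matched), with PSMA5 5.68-fold lower, and small nucleolar RNA host genes gave 6 lower and 5 higher among 15 (median -0.30, percentile 4.76, and 0.63 with 3' GC matched), a median that was near 0 at a limit of 100 counts.

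Mitochondrial ribosomal proteins gave 22 lower and 16 higher among 76 (median 0.053, negative under total-count scaling), with MRPL13 9.73-fold lower. Translation initiation factors gave 16 lower and 10 higher among 53 (median -0.12), with EIF2D 10.1-fold lower. The 225 zinc finger genes gave 53 higher and 33 lower. Their median was 0.11 (percentile 99.9, and 99.99 with 3' GC matched) and 0.12 after centring on 3' GC. Total-count scaling turned it to -0.019, where the median of all compared symbols lay at -0.16. Solute carriers gave 42 higher and 42 lower among 191 (median 0.11, or -0.027 after centring on 3' GC). RAB GTPases gave 9 higher and 7 lower among 46 (median -0.067), kinesins 5 and 5 among 29 (median -0.23), and ubiquitin-specific proteases 5 and 10 among 43 (median -0.020).

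Of the tests below, 3 were chosen only after their result was seen: counting error, the count of genes without pseudogenes, and the ADGRF4 reads. The patterns themselves, the centring on 3' GC and 1 added condition on the immediate early genes also followed from what was seen in the data. The first pattern is the number of genes at least 2-fold apart between the libraries. Counting error is argued against for the 1177 most abundant symbols, where the SD of log2 ratios was 19.5 times that of Poisson draws. That contrast says nothing about symbols with low counts. Across all compared symbols, Poisson draws gave at most 2 that were 2-fold apart, against 923 higher and 1219 lower. This argues against counting error alone, although the draws leave out duplicate reads. The trend with the GC content of 3' ends as the whole cause passed the preset test by a narrow margin only. After centring, 53.4% of the genes stayed 2-fold apart, against the bound of 50% set beforehand. The SD of the log2 ratios was 0.77 before centring and 0.69 after, against 0.15 for counting error without duplicate reads. The trend as measured, on the longest annotated transcript of each symbol, therefore left most genes' spread in place. Where another 3' end was read, centring could not remove an effect of its base composition. Base composition as the whole cause is therefore not decided by these values. The trend may account for much of the higher side, where 240 of 872 genes remained, and for less of the lower side, where 844 of 1159 did. A difference in library preparation and an effect of the siRNAs both stay open, because treatment and library are the same split.

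The second pattern is the 20 abundant genes (mean of at least 1000 counts, with a 3' GC value) that were at least 4-fold lower after ADGRF4 siRNA, such as TMSB4X, PFN1, EEF1A1, SLC25A5 and RPL34. Their median log2 ratio was -2.47, and the GC trend gave a median of -0.35 in the genes of lowest 3' GC. The genes were chosen for being at least 4-fold lower, so that contrast was fixed in advance. The median of -2.29 after centring was fixed too, since a trend of that size could not bring such genes near 0. Neither value tests the trend as the whole cause. A named processed pseudogene exists for 60% of them, against 26.2% in random lists matched on count (percentile 99.975), so reads shared with pseudogenes may contribute for those 12. For the other 8, among them HES1, BCHE, CYP24A1 and MGST3, no copy is named after the gene. CAPN12, EIF3M and OCIAD1 of the 8 are overlapped on the other strand. Copies under other names were not counted, so shared reads are not excluded for the 8. Among all compared genes with a 3' GC value, the median log2 ratio was -0.0086 with no named processed pseudogene. It was -0.14 with 1 to 4 and -0.073 with 5 or more, so ratios did not fall steadily with the number of copies. Whether shared reads lowered any of the 20 genes was not tested, and neither was an effect of the siRNAs.

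The third pattern is the lower level of immediate early genes, a hypothesis from the fixed lists. The criterion set before the result, a median within the central 95% of random lists matched on count and 3' GC, was met at percentile 10.2. The list lay inside the central 95% with count alone matched too (percentile 2.85), so meeting it tells nothing about the GC trend. After the result was seen, a further condition was added, that centring bring the median to under 0.5 of its distance from 0, and it was not met: the median was -0.40 (bootstrap interval over genes -0.81 to 0.096) after centring and -0.29 before. At least 1.5-fold lower were 11 genes after centring and 10 before, with 2 higher each time. With 22 genes and an interval that spans 0, the trend as the cause cannot be told apart from its absence. Loss of the ADGRF4 transcript as the cause cannot be told apart from other differences between the libraries either, because the control library had only 3 ADGRF4 reads.

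CCDC73 had 1734 control and 230 knockdown counts, and EIF3M, whose exons it overlaps on the other strand, had 1785 and 243. The log2 ratios were -2.64 for CCDC73 and -2.60 for EIF3M. With values this close, the lower level is not assigned to either gene alone. Whether the same reads were counted for both genes was not tested. Other pairs on opposite strands differed in level, and sharing of reads was not tested for them either. CAPN12 had 10724 and 1131 counts beside 17501 and 7533 for ACTN4. WDR38 had 2642 and 7776 beside 10247 and 21085 for RPL35.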
